A study of Mus musculus with 6 samples.

How the data were processed

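RNA from 3 undifferentiated and 3 differentiated samples of the mouse line MC3T3-E1 was labelled with biotin and measured on 1-colour Affymetrix Mouse Gene ST arrays, with 1 array per sample. Groups and replicate numbers come from the sample titles, and growth and induction conditions from the labels' protocols. The series' design text calls the replicates independent, without saying what separated them.

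The table of values holds log2 expression as the authors deposited it, made with RMA (background correction, quantile normalization and summary per probe set) per the submitters' processing notes, which give no version. The log base is not stated beyond the name of the method, which works in log2. A further step is seen only in the values: each of the 28856 probe sets has a median of 0 over the 6 arrays, to within 1e-06. Such centring subtracts 1 constant per probe set and leaves differences between arrays as they were, but it removes the level, so signal over background is unknown and no filter on dim probe sets can be made. No scanner files were used here, and the direction of the scale was taken as higher for more RNA. No per-array depth applies, and the number of arrays limits the precision.

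Probe sets were named from the platform's annotation, with symbols updated by gene ID through a RefSeq gene table of assembly GRCm38.p6. Of the 28856 probe sets, 21789 name 1 gene, 1621 several and 5446 none, and 21698 of the first kind were matched by gene ID. Probe sets naming several genes or none entered no gene result. Coordinates are not printed because the build behind the array's annotation is not given in the sources used here. No probe set had values identical to another's.

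Several probe sets of a gene were averaged, which affected 999 of the 19938 genes tested. The plan made before the data were examined took the brightest probe set, which centred values cannot give, and listed the mean as its alternative. Differentiated minus undifferentiated was fitted with limma (lmFit and eBayes, two-sided, no replicate block), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A second count also required a log2 fold change of at least 1 in size, which is 2-fold. Errors are limma's moderated standard errors.

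The 30 gene lists were fixed from textbook knowledge before the data were examined. They cover bone, osteocyte, mineral and matrix genes, glucocorticoid response, clock, cell cycle, signalling, metabolism, inflammation and markers of other cell types, and some genes stand in more than 1 list. Genes of the lists outside the tested set were not analysed here. Each list was tested with limma's camera against all other genes (preset correlation 0.01, Benjamini-Hochberg over the lists), again with a correlation estimated per list, and with fry, which asks whether members move one way without comparing them with other genes. Members were counted by their adjusted p over all genes and again adjusted over the list alone.

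Genes named in the text were chosen by a rule fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among genes past both thresholds whose groups do not overlap, passing over predicted or unnamed loci. It adds up to 4 members per list with the largest changes past the threshold, and a set of bone, glucocorticoid, proliferation and lineage genes whatever their result. That set held 16 genes, of which 13 were analysed here. The bone genes Runx2, Bglap and Spp1 of the set were not among the genes tested. A few members outside the rule are named where a count was small, a range needed its ends or a list moved both ways. These (Smc4, Fam107a, Cdt1, Podnl1, Clock, Ciart, Cxcl5, Ccn1, Ccn2, Ankrd1, Tead1 and the falling collagens) were chosen after their values were seen, as were those of the closing observations.

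In the closing observations, list medians carry 95% intervals from 10000 bootstrap draws over genes and are set against a bound of 0.5 in size. The fit was tested on simulated data with the spread of the real genes. With 50 genes changed at each size, it called 12% at a log2 fold change of 0.25, 76% at 0.5, 98% at 1 and 100% at 2, and 6 of 19720 unchanged genes. The 18 measured glycolysis genes were shifted as well and are not among the unchanged ones. Far fewer genes were changed than the 35.5% called in the real data, and noise was drawn independently per gene. These shares therefore need not hold for the real data. Alternatives were the replicate number as a block, quantile, median and cyclic loess scaling of the deposited values (which, being centred, are not the usual input of these methods), every probe set tested, array weights, each array left out, the estimated correlation and fry. Added after seeing the data were the lowest-numbered probe set per gene, only genes with 1 probe set, and robust eBayes. The planned filters on dim genes and the intensity trend need a level and were not run. R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9 were used.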

Results

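Gene expression was measured on 6 Affymetrix whole-transcript mouse arrays hybridised with RNA from MC3T3-E1, a mouse calvarial line of osteoblast precursors that lays down bone-like matrix when induced. The undifferentiated group held 3 arrays of cells kept in α-MEM lacking ascorbic acid, with 10% serum. The differentiated group held 3 arrays of cells taken at confluence and kept for 14 days in DMEM with dexamethasone at 0.1 µM, β-glycerophosphate at 10 mM, ascorbic acid-2-phosphate at 0.2 mM, sodium pyruvate at 1 mM and 10% serum. The labels call the replicates of each group independent. Base medium, time at confluence and the induction compounds differ between the groups together, so the comparison covers all of them at once.

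The deposited values ran from -3.59 to 3.62, and every probe set had a median of 0 over the 6 arrays to within 1e-06. Differences between arrays can therefore be read, but the level of a gene cannot, and no detection call can be made. Array medians over all probe sets were -0.00450, -0.00499 and 0.00453 in undifferentiated replicates 1 to 3 and 0.00838, -0.00467 and 0.000670 in differentiated replicates 1 to 3. The first principal component of the 19938 genes held 89.8% of the variance and separated the groups, with scores from -36.3 to -29.2 in undifferentiated and from 31.6 to 34.9 in differentiated arrays. The second held 3.44%. Across genes, which are not independent replicates, Pearson correlations of the centred values were 0.803 to 0.873 within groups. Between groups they were -0.890 to -0.850, where the centring itself makes values negative. The group difference, which dominates the centred values, also raises the within-group correlations. They therefore do not measure the agreement of replicates alone. Undifferentiated replicate 3 had the largest residual SD around its group mean, 0.0947 against 0.0745 to 0.0867 in the other arrays.

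The comparison asked which genes differ between uninduced cells and cells after osteoblast induction. The largest rise was in Apod and the largest fall in Hs6st2, and all 39 measured genes of G2/M and mitosis fell. The lipocalin Apod (probe set 10439009) was 127-fold higher in differentiated cells, with a log2 fold change of 6.99 ± 0.08 (SE, 3 arrays per group, adjusted p = 3.60e-10). The transglutaminase subunit F13a1 (probe set 10408693) was 116-fold higher (6.85 ± 0.06, adjusted p = 8.16e-11), and the collagenase Mmp13 (probe set 10583044) 49.9-fold higher (5.64 ± 0.07, adjusted p = 3.60e-10). Mki67 (probe set 10568714), the proliferation antigen Ki-67, was 7.70-fold lower (-2.94 ± 0.08, adjusted p = 4.24e-08).

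In all, 7070 of 19938 genes (35.5%) changed at an adjusted p under 0.05, 3270 higher and 3800 lower. Of these, 959 changed at least 2-fold, 505 higher and 454 lower. Without adjustment, 8584 genes had a p under 0.05. The 3 arrays of one group lay wholly above those of the other for 9210 genes (46.2%), where chance gives 10%. Among the 7070 changed genes, the groups overlapped for 77. The median log2 fold change of all genes was 0.02.

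The other leading rises were the keratan sulphate proteoglycan Lum (5.24 ± 0.09), the orphan nuclear receptor Nr4a1 (4.68 ± 0.13), the transmembrane glycoprotein Gpnmb (4.64 ± 0.09), angiotensinogen Agt (4.63 ± 0.08), Cped1 (4.49 ± 0.07), the retinaldehyde dehydrogenase Aldh1a1 (4.11 ± 0.08), Col15a1 (3.92 ± 0.07), the aminopeptidase Enpep (3.85 ± 0.12) and Itgbl1 (3.74 ± 0.10). Adjusted p-values of these 9 genes were 4.67e-08 or lower. The falls were led by the heparan sulphate 6-O-sulphotransferase Hs6st2 (-3.04 ± 0.07). Cdsn (-2.95 ± 0.17), the hyaluronan-binding protein Cemip (-2.83 ± 0.09) and Cip2a (-2.83 ± 0.11) were also among the leading falls. Genes of mitosis and the cell cycle made up most of the rest: Cenpe (-2.95 ± 0.09), Plk1 (-2.90 ± 0.07), Tpx2 (-2.88 ± 0.11), Hmmr (-2.83 ± 0.07), Pclaf (-2.82 ± 0.12) and Ect2 (-2.81 ± 0.07). The histone H4c6 (-2.95 ± 0.11) has near-identical copies in the genome, so its probe set can read several of them. By the rule that chose these genes, all 3 arrays of one group lay above all 3 of the other in each.

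**Figure D1:**
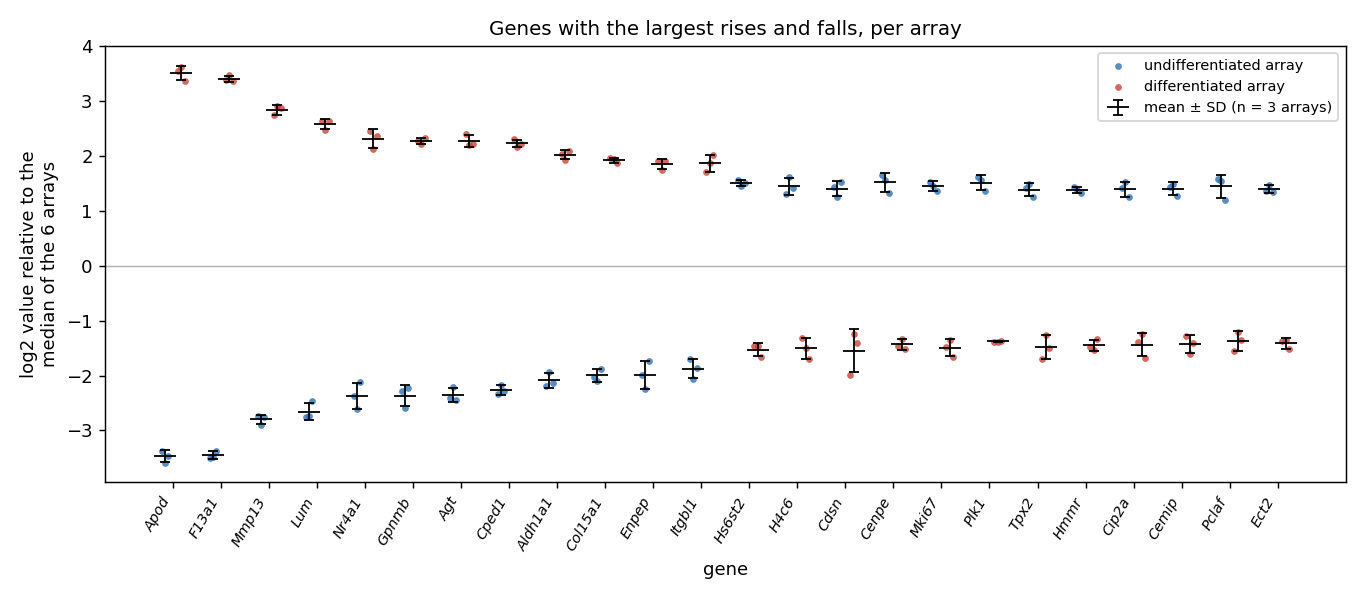
The 12 genes with the largest rise and the 12 with the largest fall, differentiated against undifferentiated, 3 arrays per group. By log2 fold change, Apod (6.99) and F13a1 (6.85) lead the rises and Hs6st2 (-3.04) leads the falls.

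Bone genes moved in both directions. Of 23 measured members of the osteoblast and bone matrix list, 9 rose, 5 fell and 9 did not pass (10 higher and 6 lower when adjusted over the list alone). Ibsp (probe set 10523701), the bone sialoprotein, was 8.72-fold higher (3.12 ± 0.09, adjusted p = 4.67e-08), and Alpl (probe set 10517587), the tissue-nonspecific alkaline phosphatase, 1.95-fold higher (0.96 ± 0.08, adjusted p = 1.49e-05). Osteomodulin Omd (2.27 ± 0.08), the pyrophosphate transporter gene Ank (2.25 ± 0.07) and periostin Postn (1.67 ± 0.05) also rose. Col1a1, a chain of type I collagen, was 1.32-fold lower (-0.40 ± 0.07, adjusted p = 0.00146). The osteoblast transcription factor gene Sp7 was 1.32-fold lower (-0.40 ± 0.07, adjusted p = 0.00257), but after cyclic loess its value was -0.19 and the call was lost (adjusted p = 0.150; other settings gave 0.000613 to 0.0132). The list as a whole had a median log2 fold change of 0.08 and did not pass camera (adjusted p = 0.0807), except without differentiated replicate 1 (0.0491, with 0.0522 to 0.0991 without each other array).

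In the osteocyte list 7 of 17 measured members rose, 1 fell and 9 did not pass (7 and 1 when adjusted over the list alone). Dmp1 (probe set 10523693), an acidic matrix phosphoprotein of osteocytes, was 10.9-fold higher (3.44 ± 0.20, adjusted p = 1.62e-06). The secretory kinase Fam20c (2.19 ± 0.10) and podoplanin Pdpn (1.29 ± 0.07) rose, and Hyou1, an endoplasmic reticulum chaperone, fell (-0.66 ± 0.09). Phex (-0.05 ± 0.05, adjusted p = 0.539) and Mepe (0.00 ± 0.05, adjusted p = 0.959) did not pass, and whether they were expressed cannot be read from centred values. The list passed camera (median 0.10, adjusted p = 0.0366), but not without undifferentiated replicate 2 (0.0816, with 0.0176 to 0.0415 without each other array), and its adjusted p = 0.403 with an estimated correlation. Of 22 measured genes of phosphate and mineral handling, 10 rose, 2 fell and 10 did not pass (10 and 3 when adjusted over the list alone). Dmp1, Ank and Fam20c count here too, and Vdr, the vitamin D receptor, fell (-2.11 ± 0.07). This list passed camera with a median of 0.12 (adjusted p = 0.00991), and had adjusted p = 0.278 with an estimated correlation.

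**Figure D2:**
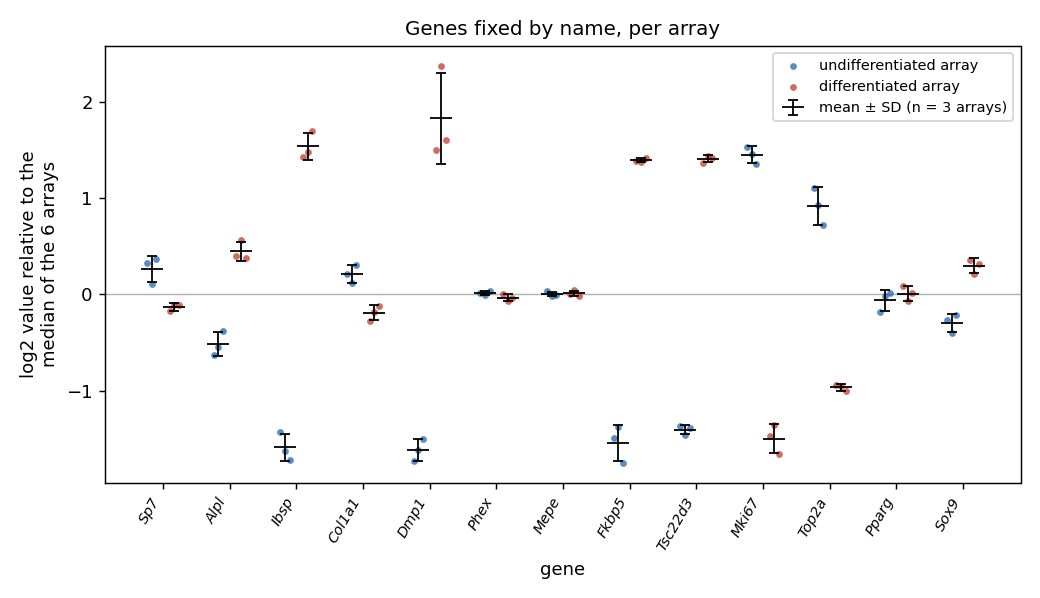
Centred log2 values of the 13 measured genes of the 16 chosen in advance for bone, glucocorticoid response, proliferation and other lineages. One point is drawn per array, with bars at the group means, for undifferentiated and differentiated arrays. Ibsp, Dmp1, Fkbp5 and Tsc22d3 lie higher in all 3 differentiated arrays, Mki67 and Top2a lower, and Phex, Mepe and Pparg overlap between groups.

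Of 27 collagen chains, 14 rose, 5 fell and 8 did not pass (14 and 5 when adjusted over the list alone). Besides Col15a1, rises were seen in the basement membrane chain Col4a1 (1.92 ± 0.09), the fibrillar chain Col11a1 (1.79 ± 0.07) and Col8a1 (1.67 ± 0.05). The falls were Col5a2, Col5a1, Col4a5, Col1a1 and Col8a2, from -0.83 ± 0.05 in Col5a2 to -0.24 ± 0.05 in Col8a2. The collagen list had a median of 0.32 and passed camera (adjusted p = 6.46e-04, but adjusted p = 0.438 with an estimated correlation). Of 14 small leucine-rich proteoglycans, which bind and space collagen fibrils, 10 rose, 1 fell and 3 did not pass (10 and 1 when adjusted over the list alone). Lum led them, followed by Aspn (3.00 ± 0.06), Omd and Dcn (1.66 ± 0.12), while Podnl1 fell (-0.30 ± 0.06). Their median was 0.72 (adjusted p = 1.71e-05, and adjusted p = 0.135 with an estimated correlation).

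Among 27 matrix proteases and inhibitors, 13 rose, 6 fell and 8 did not pass (14 and 6 when adjusted over the list alone). Mmp13, the collagen-cleaving cathepsin Ctsk (3.21 ± 0.06) and the plasminogen activator Plat (2.35 ± 0.12) rose, and the aggrecanase Adamts5 fell (-2.43 ± 0.09). The list passed camera with a median of 0.17 (adjusted p = 0.00131, and adjusted p = 0.0862 with an estimated correlation). Collagen modification and crosslinking genes split, 10 of 26 higher, 9 lower and 7 not past the threshold (12 and 9 when adjusted over the list alone). The prolyl hydroxylases P3h2 (-1.49 ± 0.07) and P4ha2 (-0.84 ± 0.06) and the collagen chaperone Serpinh1 (-0.79 ± 0.07) fell, while P4ha3 rose (0.69 ± 0.07). That list did not pass camera (adjusted p = 0.843). Its median of 0.09 and camera's direction were upward, and its mean of -0.04 and fry's direction downward.

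Every measured glucocorticoid response gene rose, 24 of 24 (24 when adjusted over the list alone), 13 of them at least 2-fold. The FK506-binding protein Fkbp5 (probe set 10449452) was 7.63-fold higher (2.93 ± 0.09, adjusted p = 4.67e-08), and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, 7.01-fold higher (2.81 ± 0.05, adjusted p = 6.41e-09). Errfi1 (3.29 ± 0.06), a feedback inhibitor of EGF receptor signalling, and the kinase Sgk1 (2.90 ± 0.11) rose as well, and the smallest rise was Fam107a (0.23 ± 0.07). The list median was 1.13, and camera's adjusted p was 3.47e-16 with the preset correlation and 0.0452 with an estimated correlation. Of 17 circadian clock genes, 9 rose, 2 fell and 6 did not pass (9 and 2 when adjusted over the list alone). The repressors Bhlhe41 (2.72 ± 0.06), Bhlhe40 (1.99 ± 0.07), Per1 (1.99 ± 0.07) and Per2 (0.78 ± 0.10) rose, and Clock (-0.21 ± 0.06) and Ciart (-0.36 ± 0.11) fell. The falls numbered 0 to 1 when any array but differentiated replicate 2 was left out. Per1 is also in the glucocorticoid list. The clock list had a median of 0.30 (adjusted p = 5.67e-04, but adjusted p = 0.124 with an estimated correlation).

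Cell cycle genes fell as a group. All 39 measured genes of G2/M and mitosis fell, each at least 2-fold (39 when adjusted over the list alone), from -2.95 ± 0.09 in Cenpe to -1.14 ± 0.07 in Smc4. Top2a, the mitotic topoisomerase, fell by 1.88 on the log2 scale (SE 0.09, adjusted p = 5.79e-07), and its pair of probe sets differed in size, -2.73 and -1.04. Of 38 genes of G1/S and DNA replication, 37 fell and 1 did not pass (37 when adjusted over the list alone). Leaders were the replication helicase subunit Mcm5 (-2.17 ± 0.09), the ribonucleotide reductase subunit Rrm2 (-2.15 ± 0.12), the polymerase subunit Pole (-2.03 ± 0.07) and Mcm3 (-2.01 ± 0.11). The one not past the threshold was Cdt1 (0.21 ± 0.09), and 1 gene of the list was higher without undifferentiated replicate 2. Medians were -2.49 for G2/M (camera adjusted p = 7.02e-38, but adjusted p = 0.0862 with an estimated correlation) and -1.54 for G1/S (9.86e-25, but adjusted p = 0.135 with an estimated correlation). Cell cycle inhibitors moved both ways, with 8 of 18 higher, 5 lower and 5 not past the threshold (8 and 6 when adjusted over the list alone). Btg2 (2.44 ± 0.12), Gas1 (1.87 ± 0.10) and Gadd45a (1.56 ± 0.09) rose and Gadd45b (-1.50 ± 0.07) fell. Their list did not pass camera (median 0.10, adjusted p = 0.445).

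Of 24 YAP and serum response targets, 13 rose, 7 fell and 4 did not pass (13 and 7 when adjusted over the list alone). The largest rises were immediate early genes, Egr2 (3.46 ± 0.09), Egr1 (2.75 ± 0.08), Egr3 (2.61 ± 0.11) and Ier3 (2.42 ± 0.12). They answer growth factors and other acute stimuli rather than YAP alone. Ccn2 (1.72 ± 0.08) and Ccn1 (1.18 ± 0.09) rose too, while Ankrd1 (-1.35 ± 0.11) and Tead1 (-0.77 ± 0.06) led the 7 falls. The list passed camera with a median of 0.34 (adjusted p = 0.00991), and had adjusted p = 0.313 with an estimated correlation. Its rise cannot be read as a common rise of YAP targets.

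In the Wnt pathway 12 of 41 genes rose, 6 fell and 23 did not pass (12 and 6 when adjusted over the list alone). The co-receptor Lrp5 (1.31 ± 0.07) and the secreted antagonists Wif1 (1.23 ± 0.10) and Sfrp2 (1.20 ± 0.07) rose, and the agonist Rspo2 fell (-1.70 ± 0.07). BMP and TGF-β signalling had 15 of 37 genes higher, 8 lower and 14 not past the threshold (16 and 8 when adjusted over the list alone). Receptors Tgfbr3 (1.89 ± 0.07) and Tgfbr1 (1.33 ± 0.07) and the activin antagonist Fst (1.30 ± 0.08) rose, and the BMP target Id2 fell (-1.28 ± 0.07). Of 18 genes of the IGF axis, 9 rose, 4 fell and 5 did not pass (9 and 5 when adjusted over the list alone). The binding protein Igfbp5 (4.01-fold, SE 0.09 on the log2 scale), Irs1 (1.42 ± 0.10, the mean of a pair of probe sets of which the lower was at 0.84) and Igf2 (1.27 ± 0.11) rose, and Pappa, a protease of IGF binding proteins, fell (-1.51 ± 0.07). Imprinted growth genes, which share Igf2, had 7 of 18 higher, 2 lower and 9 not past the threshold (7 and 2 when adjusted over the list alone). Plagl1 rose (0.85 ± 0.08), and Peg10 (-1.11 ± 0.10) and Ndn (-0.86 ± 0.07) fell. None of these lists passed camera: Wnt had a median of 0.09 (adjusted p = 0.0931), BMP and TGF-β 0.06 (0.203), the IGF axis 0.19 (0.0965) and imprinted genes 0.12 (0.0989).

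Lists of adipocyte, chondrocyte, smooth muscle and endothelial markers did not pass camera. Adipocyte genes had 4 of 19 higher, 1 lower and 14 not past the threshold (4 and 1 when adjusted over the list alone). The lipid droplet gene Plin4 (1.54 ± 0.10) and the fatty acid binding protein Fabp4 (0.46 ± 0.06) rose. Pparg, the regulator of fat cell formation, was at 0.07 ± 0.07 (adjusted p = 0.519). The median was 0.07 (camera adjusted p = 0.186), and 2 genes were higher without differentiated replicate 1 or 3. The lower genes numbered 2 after quantile, median or cyclic loess scaling, with array weights, and without undifferentiated replicate 3 or differentiated replicate 1. Chondrocyte genes had 6 of 20 higher, 1 lower and 13 not past the threshold (6 and 1 when adjusted over the list alone). The cartilage matrix gene Matn4 (2.37 ± 0.07) and Sox9 (0.59 ± 0.07, 1.51-fold, adjusted p = 1.32e-04) rose, and Col2a1, the cartilage collagen, fell (-1.01 ± 0.06). Their median was 0.09 (camera adjusted p = 0.0807).

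Smooth muscle and contractile genes had 4 of 16 higher, 4 lower and 8 not past the threshold (4 and 4 when adjusted over the list alone). Mylk (1.35 ± 0.05), Itga8 (1.08 ± 0.06), Smtn (0.99 ± 0.06) and Tagln (0.73 ± 0.07) rose, and the median was 0.02 (camera adjusted p = 0.662). Endothelial genes had 2 of 18 higher, 1 lower and 15 not past the threshold (2 and 1 when adjusted over the list alone). Flt1 rose (0.76 ± 0.05) and Ptprb fell (-0.66 ± 0.06). Vwf (0.23 ± 0.06, adjusted p = 0.0226) lost its call after cyclic loess (adjusted p = 0.124; other settings gave 0.00601 to 0.0753) and without any 1 array but undifferentiated replicate 3. Without that replicate 5 endothelial genes were higher, and without any other array 1. The endothelial median was 0.06 (camera adjusted p = 0.262).

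The macrophage and osteoclast list passed camera, with 6 of 20 higher, 1 lower and 13 not past the threshold (6 and 1 when adjusted over the list alone). Its median was 0.13 (adjusted p = 0.0199, but adjusted p = 0.289 with an estimated correlation). Ctsk led it, followed by Fcer1g (0.53 ± 0.07), Itgb3 (0.53 ± 0.10) and Cd68 (0.44 ± 0.10), of which Ctsk and Cd68 encode lysosomal proteins.

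Lysosome and autophagy genes rose, 22 of 26, with 0 lower and 4 not past the threshold (22 and 0 when adjusted over the list alone). Hexa (2.32 ± 0.07), a subunit of β-hexosaminidase, the cathepsins Ctsd (2.03 ± 0.05) and Ctsb (1.59 ± 0.07) and the sialidase Neu1 (1.66 ± 0.10) led them. The median was 1.02 (camera adjusted p = 1.04e-14, but adjusted p = 0.0862 with an estimated correlation). Oxidative phosphorylation genes fell, 22 of 32, with 0 higher and 10 not past the threshold (27 lower and 1 higher when adjusted over the list alone). Without differentiated replicate 3, 1 gene was higher. None changed 2-fold, and Cyc1 (-0.86 ± 0.08) and Ndufs4 (-0.83 ± 0.05) fell the most. Their median was -0.35 (adjusted p = 1.12e-08, but adjusted p = 0.0862 with an estimated correlation). ER stress and amino acid response genes fell in 16 of 25, rose in 3 and did not pass in 6 (17 and 3 when adjusted over the list alone). The pseudokinase gene Trib3 (-2.75 ± 0.13), asparagine synthetase Asns (-2.19 ± 0.07) and the mitochondrial serine hydroxymethyltransferase Shmt2 (-1.99 ± 0.11) fell, and the stress transcription factor Atf3 rose (2.61 ± 0.11). That list had a median of -0.36 (adjusted p = 4.01e-05, but adjusted p = 0.135 with an estimated correlation).

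Cholesterol synthesis genes were lower in 10 of 20 and higher in 4, with 6 not past the threshold (10 and 5 when adjusted over the list alone). Lanosterol synthase Lss (-0.71 ± 0.09) and mevalonate kinase Mvk (-0.60 ± 0.08) fell, and Insig1 (1.15 ± 0.07), which restrains the pathway, and Ebp (0.72 ± 0.07) rose. Rises numbered 2 without undifferentiated replicate 1 or 2 or differentiated replicate 1. The median of -0.20 did not pass camera (adjusted p = 0.104). Glycolysis genes had 8 of 18 lower, 4 higher and 6 not past the threshold (8 and 5 when adjusted over the list alone). Eno2 (1.75 ± 0.11) and the hexokinase Hk2 (1.46 ± 0.05) rose, and the lactate transporter Slc16a1 (-0.94 ± 0.16) and Pfkl (-0.71 ± 0.09) fell. Camera did not pass (median -0.12, mean -0.03, adjusted p = 0.249), and fry's direction was upward. Antioxidant genes and Nrf2 targets had 7 of 22 higher, 7 lower and 8 not past the threshold (7 and 7 when adjusted over the list alone). Heme oxygenase Hmox1 (1.28 ± 0.10) and Aox1 (1.05 ± 0.10) rose, and Me1 (-1.22 ± 0.07) and Nqo1 (-0.99 ± 0.07) fell. Their median of 0.000617 and mean of 0.03 were upward and camera's direction downward (adjusted p = 0.986).

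Chemokines and inflammatory mediators were higher in 17 of 31 and lower in 1, with 13 not past the threshold (17 and 1 when adjusted over the list alone). Cyclooxygenase-2, encoded by Ptgs2 (2.01 ± 0.10), the interleukin-1 receptor antagonist Il1rn (1.58 ± 0.06), Il34 (1.34 ± 0.08) and the adhesion molecule Vcam1 (1.25 ± 0.06) led the rises. The 1 lower gene was Cxcl5 (-0.19 ± 0.06), not called without undifferentiated replicate 1 or 2 or differentiated replicate 2 or 3. The list median was 0.29 (camera adjusted p = 1.71e-05, but adjusted p = 0.0862 with an estimated correlation). Interferon response genes had 4 of 26 higher, 3 lower and 19 not past the threshold (4 and 3 when adjusted over the list alone). Bst2 (1.01 ± 0.11), Ifit3 (0.55 ± 0.12), Rtp4 (0.44 ± 0.09) and Oasl2 (0.42 ± 0.09) rose, and the lower genes numbered 1 without differentiated replicate 2. The median was 0.06 (camera adjusted p = 0.445).

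**Figure D3:**
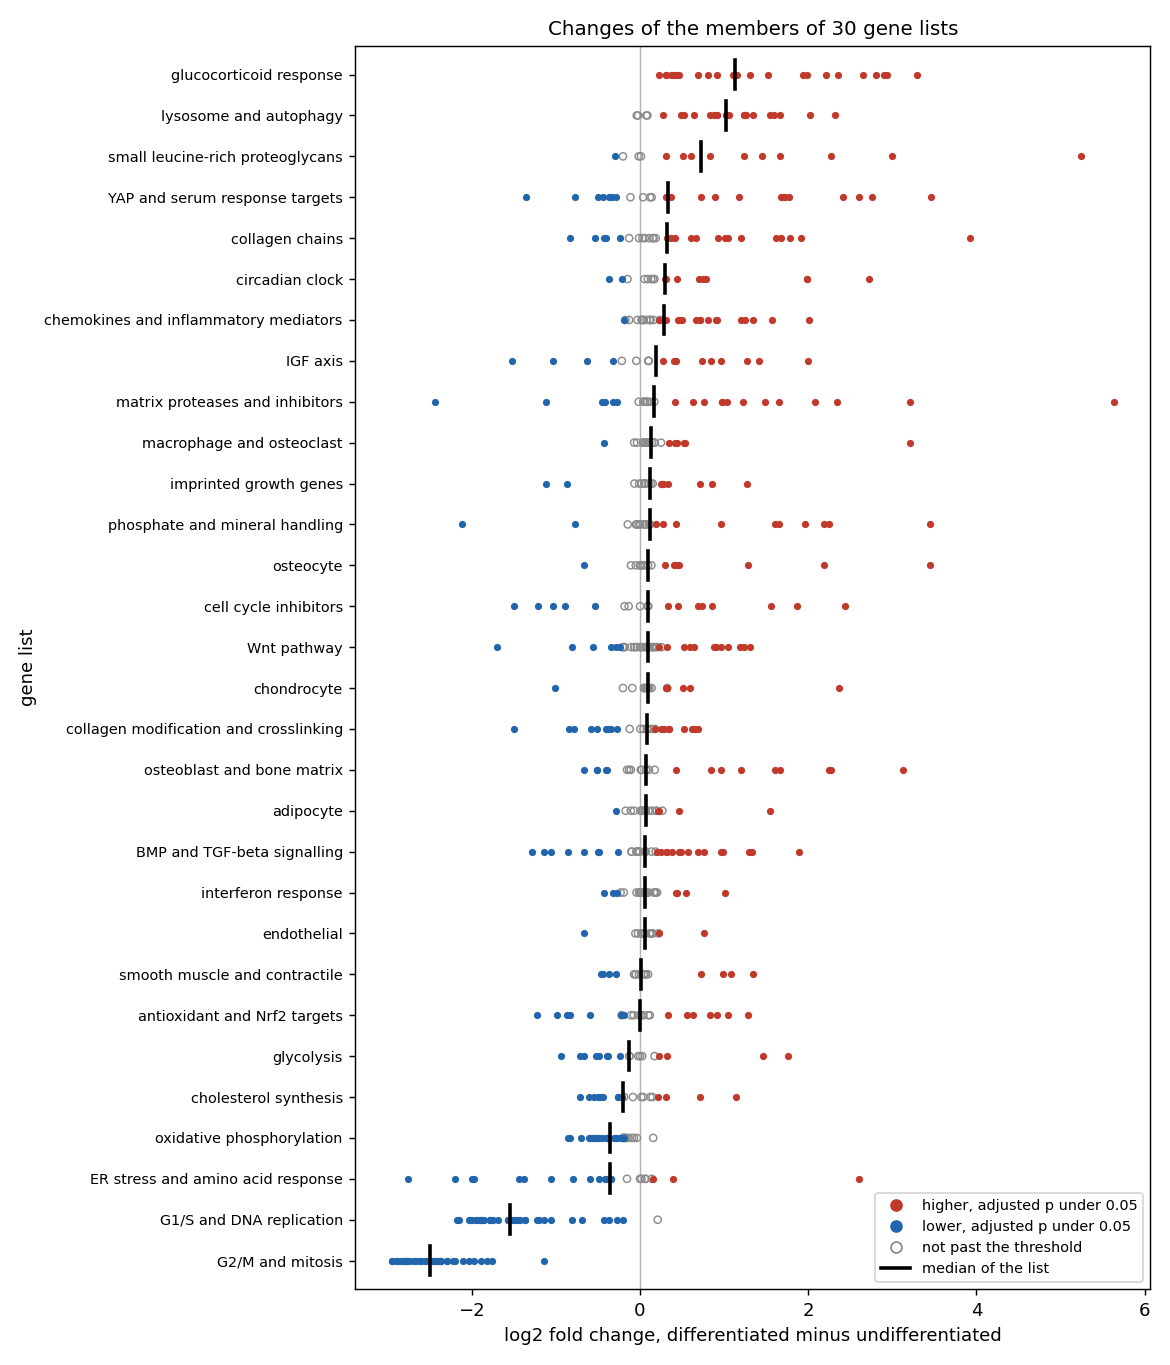
Log2 fold changes (differentiated minus undifferentiated) of the measured members of the 30 gene lists, one point per gene with a line at each list's median. The glucocorticoid (median 1.13) and lysosome (1.02) lists lie to the right and the G2/M (-2.49) and G1/S (-1.54) lists to the left.

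Of the 30 lists, 15 passed camera with its preset correlation and 1, the glucocorticoid list, with a correlation estimated for each list. At an unadjusted p under 0.05, 10 lists passed with the estimated correlation. With 3 arrays per group, an exact permutation test of a single gene cannot give a two-sided p under 0.1, so single-gene calls rest on the spread that limma shares across genes.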

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

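The test of other splits in this part was chosen after the result was seen. Probe sets outside the gene results also differed between the groups. Among 5446 probe sets naming no gene, 468 were higher and 514 lower in differentiated arrays by limma's adjusted p (18.0% changed), 48 and 53 of them at least 2-fold. The largest were probe sets 10428619 (log2 fold change 4.86 ± 0.05, adjusted p = 7.31e-09) and 10386115 (3.65 ± 0.05) upward, and 10562637 (-3.25 ± 0.06) and 10411739 (-3.22 ± 0.08) downward. Among 1621 probe sets naming several genes, 128 were higher and 341 lower (28.9% changed), 9 and 39 of them at least 2-fold.

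The 6 arrays make 10 splits into groups of 3, and 1 of the 10, the real one, gave as many as 7070 changed genes. The highest count among the other splits was 0 by limma's adjusted p, with 171 to 905 genes at an unadjusted p under 0.05 against 8584 in the real split. A share of splits under 0.1 cannot be reached with so few. Every other split also mixes arrays of both groups, which puts the group difference into its residual spread. Few calls were therefore bound to follow, and the counts of these splits do not measure chance.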

How the results depend on the processing

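Counts of changed genes stayed within 1.5 times of 7070 under each setting run. They ran from 6964 to 7391 over 19938 genes with other scalings, array weights, robust eBayes or the lowest-numbered probe set (the last pair added after seeing the data), and were 8859 over all 28856 probe sets and 6519 over the 18939 genes with 1 probe set (also added later). Leaving out single arrays gave 6003 to 7523. Higher genes made up 43.6% to 48.6% of the changed ones across settings, and the median log2 fold change of all genes 0.0125 to 0.0273. After cyclic loess, 2 of the 7070 calls were past the threshold in the opposite direction. Of values for named genes under the alternatives, 1902 stayed called in the same direction or stayed uncalled, and 12 lost the call. The 12 belong to Sp7, Vwf and the adipocyte list's Fasn (0.23 on the log2 scale, adjusted p = 0.0304), whose call was lost in 5 of the fits without 1 array (adjusted p = 0.0520 to 0.114) and held without differentiated replicate 2 (0.00576). No called list or named gene turned direction. With fry, 3 lists that passed neither test (glycolysis, collagen modification, and antioxidant and Nrf2 targets) turned direction, as did the last of these and Mepe, also not called, under some other settings.

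Replicate numbers share only a number: deviations of same-numbered arrays correlated at -0.00133, 0.0692 and 0.162 across genes, and not every array correlated best with its own number. With the replicate block 7162 genes changed, 6771 of them also called without it. The chondrocyte list passed camera with the block (adjusted p = 0.0468, against 0.0807). Over all camera settings its adjusted p was 0.0468 to 0.403, and fry, which makes no comparison with other genes, gave 0.00525. The block changed no other list's call.

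With an estimated correlation, 14 lists lost their call in camera: matrix proteases, G2/M, chemokines, oxidative phosphorylation and lysosome (adjusted p = 0.0862 each), circadian clock (0.124), proteoglycans, G1/S and ER stress (0.135 each), phosphate (0.278), macrophage and osteoclast (0.289), YAP and serum response (0.313), osteocyte (0.403) and collagen chains (0.438). The estimate counts how members vary together, and it rests on 6 arrays. For matrix proteases it was -0.0118, below the preset 0.01, so a higher correlation among members does not account for every lost call. With an estimated correlation, camera also rests on the few residual degrees of freedom of the 6 arrays, not on the number of genes. That alone raises p-values, and its share in the lost calls was not separated. For the glucocorticoid list, camera's unadjusted p rose from 3.47e-17 to 0.00151 with an estimate of 0.0202. With fry, which makes no comparison with other genes, 9 lists passed that camera did not call: osteoblast (1.13e-04), IGF (0.00229), smooth muscle (0.00288), chondrocyte (0.00525), BMP and TGF-β (0.00529), imprinted (0.00964), adipocyte (0.0146), Wnt (0.0166) and cell cycle inhibitors (0.0268). Leaving out single arrays, the osteocyte list ran from 0.0176 to 0.0816, losing its call without undifferentiated replicate 2, and the osteoblast list from 0.0491 to 0.0991, passing only without differentiated replicate 1. The cause was not tested. List counts of higher or lower members moved by over 1.5 times in 31 cases, all from counts of 4 or fewer, and by less in 809.

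The planned filters on dim genes, the brightest probe set per gene and the intensity trend were not run, since centred values hold no level. For the same reason signal over background, which limits what an array can measure, is unknown.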

Other observations

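The gene lists of this part were written after the table of all genes had been seen. The tests of macrophage genes, of rescaling and of ER chaperones were chosen after their results were seen. Complement genes held 5 higher, 0 lower and 8 not past the threshold among 13 measured. The higher ones were C1s1 (3.14 on the log2 scale), C1ra (1.28), Masp1 (1.18), Cfb (0.71) and C4b (0.54), of which C1s1 and C1ra encode proteases of the first complement component. Retinoid metabolism had 6 of 16 higher and 1 lower. Besides Aldh1a1, which makes retinoic acid, the alcohol dehydrogenase Adh1 rose by 3.25, the binding protein Crabp2 by 0.97 and Aldh1a3 by 0.75, and the receptor Rarg fell (-0.25).

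Of 8 measured genes of the angiotensin system 4 rose: the precursor Agt (4.63), the peptidases Enpep (3.85) and Mme (0.97), and the prorenin receptor Atp6ap2 (1.04). Of the receptor tyrosine kinases bound by Gas6, Mertk (3.56) and Axl (0.73) rose, and Tyro3 was at -0.07 without passing. Their ligands Gas6 (3.09) and Pros1 (1.03) rose too. Both lists were built around genes already seen to change, so their counts are not independent evidence. The lists used below were also written after the gene table was seen, so their counts and medians are not fully independent evidence either.

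Immediate early genes such as Egr1, Egr2 and Nr4a1 were higher after 14 days, although they usually answer acute stimuli. Heat shock or handling stress at harvest stays open. Heat shock genes had a median log2 fold change of 0.11 (0.1131, 95% bootstrap interval over genes -0.412 to 0.330), below the bound of 0.5 set beforehand. Their members went both ways, so the median decides nothing. Of 14 heat shock genes 6 were higher, among them Dnajb4 at 1.08, Hspb1 at 0.88 and Hspa1a at 0.33. The 5 lower ones included Hspd1 at -0.81, Hsp90aa1 at -0.57 and Hsph1 at -0.48. Other primary response genes shifted by 0.999 (0.707 to 1.72; 26 of 28 higher), among them Arc (2.55), Nr4a3 (2.28) and Jun (2.17), so the pattern may be a wide primary response. Lasting ERK signalling cannot be told apart from it, since the ERK feedback genes had a median of 0.820 with an interval that spans the bound (0.416 to 2.03; 13 genes, 12 higher). Medium, time since feeding and induction were not separated by the design.

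Lysosomal genes and the macrophage and osteoclast list were higher in differentiated cells by camera (with an estimated correlation, adjusted p = 0.0862 and adjusted p = 0.289). Macrophages as the source of the whole rise would bring their abundant transcripts. Macrophage genes other than those of the lysosome list had a median of 0.0995 (0.0294 to 0.251, 4 of 15 higher, 0 lower). With Lyz2 at 0.04, this argues against macrophages as the whole source. The higher ones were Cd53 (0.66), Fcer1g (0.53), Cd33 (0.28) and Laptm5 (0.22, itself a lysosomal membrane protein). These values alone do not exclude a small share, but the samples were a cultured line of osteoblast precursors, not a tissue. Rescaling after the fall of cell cycle genes would shift all other genes alike. The lysosome list's median lay 1.001 (0.738 to 1.22, 26 genes) above theirs. The median log2 fold change of all genes was 0.02, so this difference repeats the list's rise and is no separate test. A shift common to all genes cancels in it and cannot alone make it. A shift that depends on signal level stays open, since centred values hold no level. Further lysosomal genes had a median of 0.755 (0.632 to 0.974; 33 of 37 higher), led by Ctns (3.02), Gaa (2.03) and Naglu (1.96). A lysosome-wide programme is a hypothesis that these values are consistent with, and whether confluence or a compound of the medium set it was not tested.

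Amino acid response genes, with Trib3, Asns and Shmt2 in the lead, were lower in differentiated cells (the list by camera, but adjusted p = 0.135 with an estimated correlation). A lower load on the whole ER stress response would lower its chaperones alike. They did fall, with a median of -0.35 (-0.3471, interval -0.397 to -0.154, 13 of 18 lower), smaller in size than the bound of 0.5. Several of them, such as Hspa5 and Hsp90b1, belong to the list itself, and their values had been seen. The bound therefore does not decide on a lower load. The values show only a smaller fall of chaperones than of the ATF4 targets that follow. Further targets of ATF4, the transcription factor of amino acid shortage, had a median of -0.885 (-1.11 to -0.649; 23 of 28 lower, 3 higher), with Cth (-2.31), Aldh1l2 (-1.99) and Pck2 (-1.66) among them. The 3 higher targets were Cebpb (0.77), Nupr1 (0.51) and Ppp1r15a (0.19). In the ER stress and amino acid response list, 16 of 25 fell, but Atf3 (2.61), Dnajb9 (0.39) and Slc3a2 (0.16) rose. Ddit3 (0.07) and Fgf21 (0.02) of that list did not pass. Lower ATF4 output is a candidate explanation that these genes do not follow, and Atf4 itself was at -0.15 without passing. The amino acid supply of the 2 media and a difference in proliferation stay open, since both differ with the groups.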
